A study of Homo sapiens with 7 samples.

How the data were processed

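The data are from chromatin immunoprecipitation followed by sequencing (ChIP-seq) in C4-2B cells, an established castration-resistant prostate cancer line. Per the labels' protocols, cells were grown in charcoal-stripped serum, which is depleted of steroid hormones, and were fixed with formaldehyde. Chromatin was sheared by sonication and precipitated with an antibody against HOXB13 acetylated at lysine 13, and libraries were sequenced on an Illumina HiSeq instrument. The 7 libraries fall into 3 groups by their labels: 3 HOXB13-K13ac precipitations, 2 IgG controls (a non-specific antibody) and 2 inputs (sheared chromatin without precipitation). Replicate 1 carries the library series number 2898, and replicates 2 and 3 carry 3047. Each series number also names 1 IgG and 1 input library, and the input of 3047 shares a further tag with replicate 2.

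The deposited files are 6 peak lists, and the depth of every library is unknown, because the lists hold no read counts. Per the submitters' processing notes, CASAVA 1.4, BWA, Bowtie2 and MACS2 were used and the builds named are hg19 and GRCh37. The role of each tool, the calling threshold and the filter applied to the lists are not given in the sources used here. In the lists, as deposited by the authors, each peak has a fold enrichment at its summit, a ratio to the local background of the control. Each peak also has a −log10 p and a −log10 q, deposited by the authors as the peak caller gave them. The lowest −log10 p was between 2.01 and 2.31 in the 5 lists with more than 1 peak. Peaks were numbered by p, and the numbering had gaps. In all, 40.7% of the numbers were missing for replicate 1, 59.9% for replicate 2 against input and 93.5% for replicate 3 against input. No IgG or input library has a peak list of its own here. Coordinates are given on hg19, counted from 1.

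A list was tied to a library only by the spelling in the labels. This gave replicate 1 a list whose control is not named, and replicates 2 and 3 each a list against input and a list against IgG. Replicates 1 and 3 differ in that spelling by a single punctuation mark, so the assignment of their lists rests on it. If these 2 names were exchanged, the values would keep their size, while the replicate number and library series attached to each list would change. The sixth list, called against input, is labelled with the antibody and a suffix that matches no library, and was left out of the main replicate comparisons. It stood in for replicate 3 only in alternatives added later. Nothing in the labels says whether the replicates came from separate cultures, so no source of variation is attached to the differences between them. Whether reads of several libraries were pooled for a list is not given in the sources used here.

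Peaks were compared with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Peaks were shared when they had at least 1 bp in common. For each pair of replicates the shorter list was placed at random 1000 times within its chromosomes, keeping peak widths, over the span from the first to the last peak of any list. This permutation test was one-sided, and its smallest p is 0.001. Placements did not avoid assembly gaps or unmappable sequence, so chance overlap can be understated. Peaks of the 3 replicate lists were merged, and a merged region was called a replicated site when at least 2 libraries had a peak in it. Replicated sites 10 kb apart or less were stitched into clusters. Intervals of shares are exact 95% binomial intervals and those of densities are exact 95% Poisson intervals. Both cover counting error only, and neighbouring peaks are not independent. The code was tested on simulated lists, in which all 6000 sites placed in at least 2 of 3 lists and all 100 clusters of 5 sites were recovered. The simulated sites in these lists lay too far apart to merge with each other, so merging of neighbouring sites was not tested. Random lists of 1000 peaks gave a p of 0.05 or less in 3.0% of 200 trials. They were drawn by the same uniform placement as the permutation test, so this checks the code and not how well that placement models real peaks. Overlap counts equalled those of bedtools 2.31.1 in all 60 comparisons of the real lists.

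The tests, the lists used and the alternatives were fixed before the data were examined. In 1 setting, the overlap of a share of 0.5 of both widths, 100 placements were used rather than the 1000 fixed. Alternatives added later are named as such with their values. The 15 sites present in all 3 libraries with the highest lowest-of-3 fold enrichment, and the 10 clusters with the most sites, were named by that fixed rule. Because no genome or annotation of hg19 was used here, sites are named by position only. The genomic location of sites (promoter, exon, intron), the search for 12 motifs at summits and the test of 15 gene lists near sites were therefore not run. Alternatives changed the overlap rule (a share of 0.5 of both widths, or summits within 100 bp), the threshold (−log10 q of at least 5), the number of peaks per list, the number of libraries required, the stitching distance (20 kb) and the libraries used.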

Results

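ChIP-seq with an antibody against HOXB13 acetylated at lysine 13 was carried out in C4-2B cells. HOXB13 is a homeobox transcription factor of the prostate lineage, and C4-2B is a castration-resistant derivative of the LNCaP prostate cancer line. The deposited results are peak lists from HOXB13-K13ac libraries. They were called against sequenced input chromatin or an IgG precipitation, except that the control of the replicate 1 list is not named. The replicate 1 list held 41303 peaks, the replicate 2 list against input 45216 and the replicate 3 list against input 18232. Read depths are unknown, so the number of peaks in a list cannot be scaled to the depth of its library.

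The peaks of replicates 1 and 2 were broader and reached higher enrichment than those of replicate 3. The median peak width was 555 bp in replicate 1 (interquartile range 371 to 875), 635 bp in replicate 2 (419 to 1035) and 235 bp in replicate 3 (186 to 304). The lists covered 29.4 Mb, 38.1 Mb and 4.74 Mb of the genome. Peaks wider than 2 kb numbered 1183 in replicate 1 and 2542 in replicate 2, and replicate 3 had 0. The authors' fold enrichment had a median of 4.67 in replicate 1 (interquartile range 3.47 to 7.37), 6.50 in replicate 2 (4.71 to 10.96) and 4.40 in replicate 3 (3.98 to 5.13). Its maximum was 40.2, 89.5 and 18.0. A −log10 q of at least 5 was reached by 33334 peaks of replicate 1, 30395 of replicate 2 and 1145 of replicate 3. These values belong to single lists called on separate libraries, so no test was made between them. The control of replicate 1 is not named, so its values may refer to another kind of background than those of replicates 2 and 3.

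To ask whether the 3 libraries gave the same sites, each pair of lists was compared. Of the replicate 1 peaks, 31768 (76.9%, 95% interval 76.5 to 77.3) shared sequence with a replicate 2 peak, against 2.47% in randomly placed lists. Of the replicate 3 peaks, 5409 (29.7%, 29.0 to 30.3) lay in replicate 1 peaks and 5394 (29.6%, 28.9 to 30.3) in replicate 2 peaks, against 1.55% and 1.90% by chance. All 3 overlaps exceeded every random placement (one-sided permutation test, p = 0.001 each, the smallest that 1000 placements can give). The Benjamini-Hochberg adjusted p over the 3 pairs was also 0.001. Uniform placement ignores regional differences in mappability and gene density. Exceeding it therefore cannot tell shared antibody-specific sites from shared non-specific enrichment. When the comparison was limited to peaks with a −log10 q of at least 5, replicate 3 shared 86.3% of 1145 peaks with replicate 1 and 85.4% with replicate 2, and replicates 1 and 2 shared 77.2% of the shorter list. With the 18232 strongest peaks of each list, these shares were 27.2%, 26.8% and 84.6%. With summits within 100 bp they were 15.6%, 11.8% and 39.9%, and with a share of 0.5 of both widths 3.83%, 1.97% and 49.7%. When peaks were placed 10 kb to 100 kb from their own position, a setting chosen after seeing the data, chance was 2.85%, 3.23% and 5.74% for the same pairs.

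Within each list, the strongest peaks recurred more often than the weakest. Strength was ranked within a list and is not equal between lists. The median −log10 q of the strongest 10% was 83.6 in replicate 1, 58.0 in replicate 2 and 5.15 in replicate 3. In the 10% of each list with the highest −log10 q, 4130 of 4131 replicate 1 peaks, all 4522 replicate 2 peaks and 80.1% of 1824 replicate 3 peaks were present in at least 1 of the other 2 lists. In the 10% with the lowest −log10 q these shares were 38.5%, 13.7% and 17.9%. For replicate 3 the share was 45.8% in the next 10% after the strongest. In its later parts the share lay between 15.5% and 32.9%, without a steady fall.

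**Figure D1:**
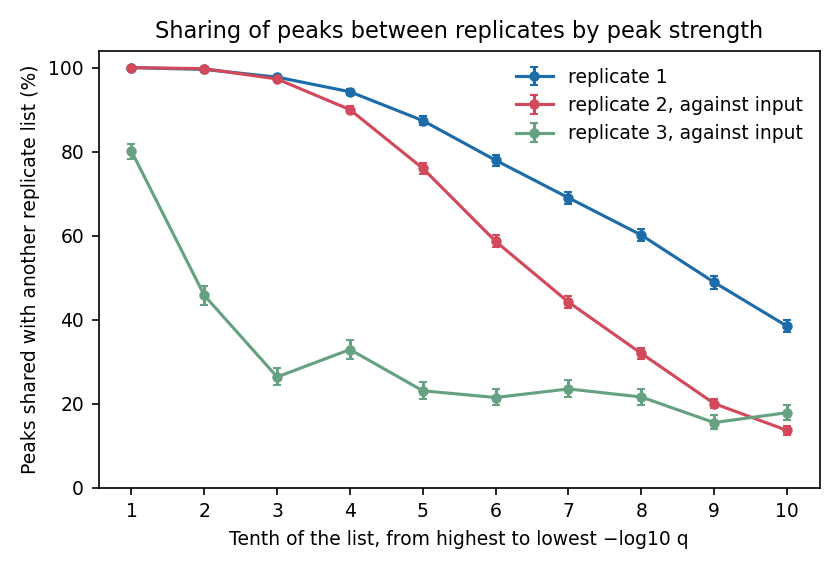
Percentage of peaks (y axis) that share at least 1 bp with a peak of either other replicate list, for 10 equal parts of each list ordered from the highest to the lowest −log10 q (x axis), with 1 line per replicate and bars for exact 95% binomial intervals. Replicates 1 and 2 start near 100% and fall to 38.5% and 13.7%, while replicate 3 starts at 80.1% and lies at 45.8% in part 2.

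Merging the 3 lists gave 65675 regions, of which 27046 (41.2%) were replicated in at least 2 libraries and 4591 (6.99%) in all 3. The replicated sites covered 33.0 Mb, with a median width of 1005 bp and a maximum of 17177 bp. Of the replicated sites, 26760 (98.9%) held peaks of replicates 1 and 2. Only 168 rested on replicates 1 and 3 alone and 118 on replicates 2 and 3 alone. Without replicate 3 there were 26763 sites. Without replicate 1, when sites had to be in both replicates 2 and 3, there were 4709, and without replicate 2 there were 4816. With summits within 100 bp there were 17926 replicated sites and, in settings chosen after seeing the data, the sites of all 3 libraries numbered 2014 by summits and 945 at a −log10 q of at least 5. Regions found in a single library numbered 9360 for replicate 1, 16659 for replicate 2 and 12610 for replicate 3.

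Regions found in more libraries were more enriched and, as merged regions, broader. The median width was 327 bp for regions of 1 library, 926 bp for regions of 2 and 1560 bp for regions of all 3. Part of this rise is built in, since a merged region spans the peaks of each library and a wider region is likelier to meet a peak of another list. The fold enrichment of a region in a library was the highest among that library's peaks in it. A wider region can hold more peaks, so part of the rise in fold enrichment may be built in as well. In replicate 2 the median fold enrichment was 4.63 (interquartile range 3.96 to 5.47) at regions it held alone, 8.49 (6.08 to 12.6) at regions of 2 libraries and 17.3 (11.6 to 24.9) at regions of all 3. In replicate 1 the corresponding medians were 3.40, 5.24 and 10.6. In replicate 3 they were 4.31, 4.42 and 5.13, a narrower span. Across the 4591 sites of all 3 libraries, fold enrichment ranked alike in replicates 1 and 2 (Spearman's rho 0.64) and less so in replicate 3 against replicate 1 (0.35) or replicate 2 (0.30). These correlations are across sites, which are not independent replicates.

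Sites of all 3 libraries were ranked by the lowest of their 3 fold enrichments. At all 15 top sites this lowest value was that of replicate 3, so replicate 3 alone set their order. The first site lay on chromosome 19, from 1652587 to 1653603. Its fold enrichment was 40.2 in replicate 1, 38.8 in replicate 2 and 18.0 in replicate 3. The next was on chromosome 11 from 74204302 to 74205246, with fold enrichments of 21.5, 37.9 and 15.8 in the same order. On chromosome 1 a site from 41706575 to 41708951 had values of 15.6, 28.6 and 15.5. On chromosome 4 a site from 1713094 to 1714516 had values of 25.7, 27.3 and 15.0. A broader region of 5648 bp on chromosome 12, from 125398530 to 125404177, had values of 17.7, 71.2 and 15.0. The other 10 of the 15 top sites ranged from 13.0 to 28.3 in replicate 1, from 18.6 to 89.5 in replicate 2 and from 12.6 to 14.4 in replicate 3. Among these 10, the site on chromosome 12 from 64797081 to 64799846 held the highest enrichment of the replicate 2 list, 89.5. Of the 15 top sites, 13 were also called in replicate 2 against IgG, the exceptions being those on chromosomes 1 (from 41706575) and 4. Only 21.5% of the 7506 peaks in that IgG list had a q of 0.05 or less. Presence in it therefore does not by itself show strong enrichment over IgG. The sites were also chosen for high fold enrichment, and the list of replicate 3 against IgG held none of them.

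Replicated sites were spread unevenly over the chromosomes. Their mean density was 9.02 per Mb. All densities were taken over the span from the first to the last peak of any list on a chromosome. This span was 34.1 Mb for chromosome 22 and 95.6 Mb for chromosome 13, and ranks over full chromosome lengths could differ. Chromosome 19 had the highest density with 25.3 sites per Mb (95% interval 24.0 to 26.6), followed by chromosome 22 with 21.2 (19.7 to 22.8) and chromosome 17 with 17.9 (17.0 to 18.8). Chromosome 19 is known as the most gene-dense human chromosome. The lowest autosomal densities were those of chromosome 4 with 5.39 (5.07 to 5.73), chromosome 13 with 5.62 (5.15 to 6.11) and chromosome 18 with 6.42 (5.87 to 7.01). Chromosome X had 5.17 (4.82 to 5.54) and chromosome Y a single site. Within single lists, chromosome 19 held 35.4 peaks per Mb in replicate 1, 32.6 in replicate 2 and 13.2 in replicate 3, where chromosome 22 was higher at 16.5. The 1 Mb window with the most sites was the second megabase of chromosome 19, from 1000001 to 2000000, with 75. It was followed by windows of 62 sites each on chromosome 1 (1000001 to 2000000) and chromosome 17 (79000001 to 80000000).

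**Figure D2:**
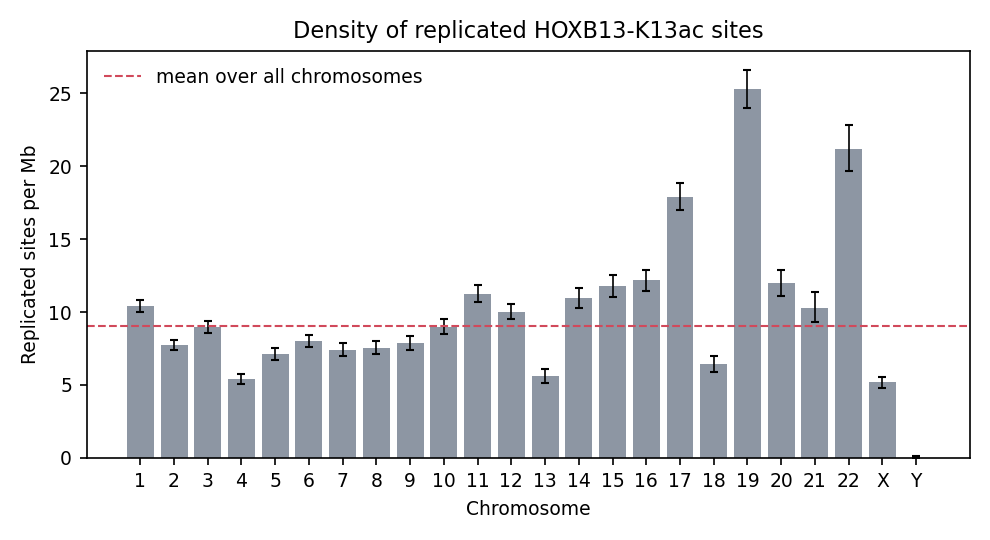
Replicated sites per Mb of the span from the first to the last peak (y axis) on each chromosome (x axis), as bars with exact 95% Poisson intervals and a dashed line at the mean of 9.02. Chromosomes 19, 22 and 17 lie highest at 25.3, 21.2 and 17.9, and chromosomes 4, 13 and X are near 5 to 6.

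The series concerns super-enhancers, which hold closely spaced regulatory sites. Clusters here were defined by spacing and number of sites alone, with no cutoff on signal, so they are not calls of super-enhancers. Sites within 10 kb of each other were stitched. This left 10964 single sites and gave 6073 clusters, of which 448 held at least 5 sites. These 448 clusters contained 10.5% of the replicated sites and had a median length of 19.9 kb. Stitching within 20 kb gave 797 clusters of at least 5 sites, and sites required in all 3 libraries gave 4. In settings chosen after seeing the data, there were 272 with peaks of a −log10 q of at least 5, 440 without replicate 3, 5 without replicate 1 and 6 without replicate 2.

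The cluster with the most sites lay on chromosome 12 from 81909211 to 82000838. It held 30 replicated sites in 91.6 kb, with 42 peaks of replicate 1, 45 of replicate 2 and 4 of replicate 3. Another cluster, of 16 sites, lay 84.3 kb before it, from 81771098 to 81824891. One more cluster on chromosome 12, from 64943582 to 65006251, held 17 sites. Elsewhere, chromosome 2 had a cluster of 20 sites from 189143193 to 189209380, and chromosome 21 one of 18 sites from 17674974 to 17726599. A cluster of 17 sites occupied chromosome 19 from 51338363 to 51412835, with 28 peaks of replicate 1, 26 of replicate 2 and 4 of replicate 3. On chromosome 16 a cluster of 16 sites from 711035 to 779341 had 16 peaks of replicate 3, the most of the 10, and 8 of its sites were present in all 3 libraries. The remaining 3 of the 10 lay on chromosome 18 (55862201 to 55930391, 16 sites), chromosome 15 (89630644 to 89683824, 15 sites) and chromosome 16 (67437576 to 67491246, 13 sites). Of the 10 clusters, 4 held no replicate 3 peak, and all 10 held peaks of replicate 2 called against IgG, from 2 to 16 each. Only 21.5% of all peaks in that IgG list had a q of 0.05 or less. Of all replicated sites, 23.2% were called in that list, so a cluster of 13 or more sites would often hold one of its peaks. The list of replicate 3 against IgG held no peak in these clusters.

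**Figure D3:**
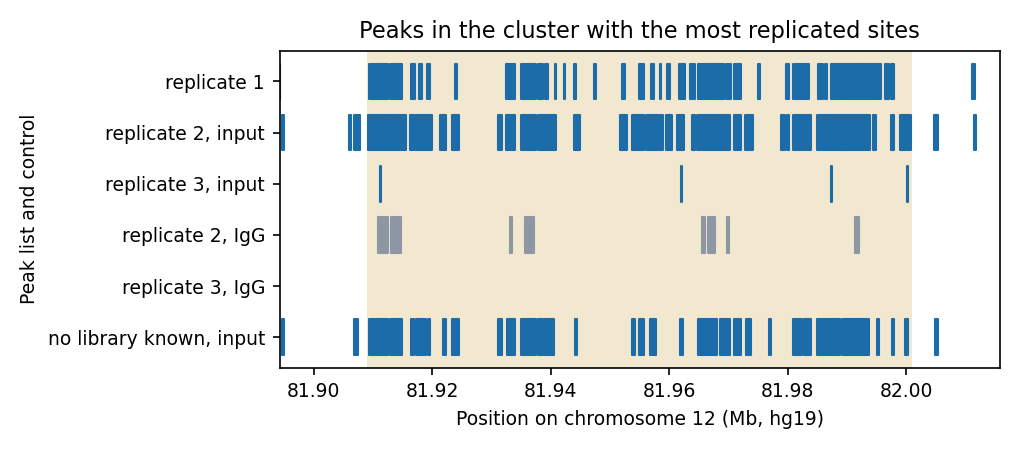
Peaks of each list (listed on the y axis, named with the control; blue against input or an unnamed control, grey against IgG) along chromosome 12 in Mb on hg19 (x axis), with the cluster from 81909211 to 82000838 shaded. Replicates 1 and 2 fill it with 42 and 45 peaks, and replicate 3 has 4.

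The IgG and input libraries are the background measurements of the study, and 2 libraries were called against both. Of the 45216 replicate 2 peaks against input, 6337 (14.0%, 95% interval 13.7 to 14.3) were also found against IgG. At a −log10 q of at least 5, where the IgG list held 203 peaks, this share was 0.661%. All 203 shared sequence with an input peak at that threshold, so the length of the IgG list limits this share. The whole IgG list held 7506 peaks with a median fold enrichment of 3.10, and 7505 of them shared sequence with a peak against input. Only 1616 of the 7506 (21.5%) had a q of 0.05 or less, compared with 99.4% of those against input. Input peaks recovered against IgG had a median fold enrichment over input of 18.5, and those not recovered 5.79. The peak most enriched over IgG by p lay on chromosome 10 from 32635316 to 32636172, with a fold enrichment of 11.6. For replicate 3 the list against IgG held 1 peak, compared with 18232 against input. That peak, on chromosome Y from 10025122 to 10025356, had a fold enrichment of 3.72 and a −log10 q of 0, and it overlapped no peak of any other list. Of the replicated sites, 6263 (23.2%, 22.7 to 23.7) were called against IgG in replicate 2, and of the sites of all 3 libraries 2369 (51.6%, 50.1 to 53.1). With the IgG peaks of a q of 0.05 or less alone, a setting chosen after seeing the data, these counts were 1501 (5.55%, 5.28 to 5.83) and 884 (19.3%, 18.1 to 20.4). Replicate 1 has no list named as called against IgG among those used here, so the IgG comparison rests on 2 libraries.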

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

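The predictions of the tests in this part were written before their results were seen, except that on filtering by the authors and the shuffled comparison of IgG folds, which were added afterwards. The 36205 peaks of the HOXB13-K13ac list that no label ties to a library are a signal outside the main replicate comparisons. No control list of the same kind was used to judge them, and they are named here because the main comparisons leave this list out. The list was called against input, with a median fold enrichment of 6.39 and a median width of 588 bp. It shared sequence with 86.9% of the replicated sites and 99.7% of the sites of all 3 libraries. Of its own peaks, 90.9% lay in the replicate 2 list, 76.7% in the replicate 1 list and 16.4% in the replicate 3 list, and 1703 (4.70%) lay in none of the 3.

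A candidate source of this list is a library shared with replicate 2, for which the prediction was at least 2 times the share of replicate 1. Of replicate 2 peaks absent from both other replicate lists, 29.5% were in it, 6.07 times the 4.86% seen for replicate 1 peaks of the same kind. This fits a shared library, but replicate 2 and this list were both called against input, and the median fold enrichment of the replicate 2 peaks tested was higher (4.63 against 3.40), so a shared control or stronger peaks stay open. For a library shared with replicate 3, 7.91% of the replicate 3 peaks absent from both other lists were in it, 4.16 times the 1.90% of peaks placed 10 kb to 100 kb from their own position, short of the 5 times set beforehand and above the 2 times that would have argued against it. No biological explanation was tested, and the list was not assigned to any library.

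Few replicate 3 peaks lay in the other lists, and 3 technical explanations were weighed. For weak peaks near the calling threshold, the prediction put the lower 5 of 10 equal parts by q within 2 times chance. Of these peaks, 20.01% lay in the list of replicate 1 or 2. That was 5.56 times the share when peaks were placed 10 kb to 100 kb from their own position. Weak peaks at true sites can also exceed chance, so this part of the prediction cannot count against weak enrichment. The strongest 10%, at 80.1%, met the other part of that prediction, so weak enrichment may account for part of the pattern. Filtering by the authors stays open, because 76.0% of the first 5000 peak numbers were in the replicate 3 list, compared with 99.98% for replicate 1 and 99.94% for replicate 2. Chromosome copy number also cannot be told apart: neighbouring 5 Mb windows correlated at 0.14 for regions of replicate 3 alone relative to those of replicates 1 and 2 alone, close to the 0.13 of replicate 1 relative to replicate 2, but chromosome means were removed first, so differences of whole chromosomes, such as the low density on chromosome X in replicate 3, were not tested.

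Fewer peaks were called against IgG than against input, and 2 explanations were weighed. A lower depth of the IgG library alone would have kept the strongest peaks. Of the 7506 strongest replicate 2 peaks against input, 67.2% were called against IgG, between the 80% and 50% set as bounds. Only 6337 input peaks were called against IgG at all, so the highest share possible lay close to the 80% bound. Of those 6337 peaks, 79.6% were among the strongest 7506. Of the 1000 strongest input peaks by p, 90.2% were called against IgG. A lower depth could therefore be part of it. This test used replicate 2 alone. In replicate 3 the list against IgG held 1 peak, which overlapped no peak against input, so none of the strongest replicate 3 peaks was kept. Signal of the IgG library at the same sites would lower the fold against IgG most at strong sites, and the ratio of the 2 folds (median 6.02, interquartile range 5.19 to 6.94) rose with the fold against input (Spearman's rho 0.79). The fold against input is part of that ratio, and shuffled IgG folds gave 0.83, so a rho above the 0.5 set beforehand says nothing here, and read depths would be needed to tell these apart.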

How the results depend on the processing

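Shared non-specific enrichment could also exceed random placement. The overlap of replicate lists stayed above chance in all 15 alternative comparisons, at 9.16 to 116.5 times chance. Its size depended on the rule: from 39.9% to 84.6% for replicates 1 and 2, from 3.83% to 86.3% for replicates 1 and 3 and from 1.97% to 85.4% for replicates 2 and 3. The lowest values for replicate 3 came from requiring a share of 0.5 of both widths (100 placements, p = 0.01 each, the smallest they can give, one-sided permutation test), which a narrow peak inside a peak over 2 times as wide cannot meet. Replicated sites numbered 27046, and 4591 when all 3 libraries were required or 17926 with summits within 100 bp. Leaving out 1 replicate at a time gave 4709 (without replicate 1) to 26763 (without replicate 3). With the list of no known library in place of replicate 3, chosen after seeing the data, there were 32197 replicated sites, and 23251 rather than 4591 in all 3 lists, but that list may share a library with replicate 2, so these counts may rest on fewer than 3 libraries. Sites of all 3 libraries numbered 945 at a −log10 q of at least 5 and 2014 with summits within 100 bp, both chosen after seeing the data. The clusters of at least 5 sites numbered 448, and 797 when stitched within 20 kb or 4 with sites of all 3 libraries. Further cluster settings chosen after seeing the data gave 5 (without replicate 1) to 440 (without replicate 3), 272 with peaks of a −log10 q of at least 5, and 642 with the list of no known library. The share of replicate 2 input peaks also called against IgG was 14.0%, or 2.49% with a share of 0.5 of both widths. At a −log10 q of at least 5 it was 0.661%. The IgG list then held 203 peaks, all shared with input peaks, so its length limits that share. Apart from this limit, the cause was not tested for any of these changes. No paired analysis was possible because the IgG and input libraries have no peak lists of their own, and 1 IgG and 1 input share the series number of both replicates 2 and 3. The alternatives for genomic location, motifs and gene lists were not run, since no hg19 genome or annotation was used here. Depth is unknown and limits all counts of peaks.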

Other observations

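Chromosome X was sparse in replicate 3. It held 136 of the 18232 replicate 3 peaks (0.746%, exact 95% interval 0.626 to 0.882), compared with 2.72% (2.57 to 2.88) in replicate 1 and 3.00% (2.84 to 3.16) in replicate 2. When replicates 1 and 2 were limited to their 18232 strongest peaks, they still had 453 and 449 on chromosome X. Relative to the median autosome, the density of peaks on chromosome X was 0.13 in replicate 3, 0.49 in replicate 1 and 0.54 in replicate 2. Density also varied between these replicates on autosomes: chromosomes 2, 4, 6 and 21 had 3.07, 2.56, 3.79 and 4.32 peaks per Mb in replicate 3 and 11.7, 8.26, 12.5 and 15.95 in replicate 1, whereas chromosomes 3 and 7 had 7.80 and 6.72 in replicate 3 and 13.9 and 11.4 in replicate 1. These comparisons were chosen after the data were seen, the intervals cover counting error only, and no test of the difference was made.

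Sites were more clustered than uniform placement along the chromosomes would give. The replicated sites formed 448 clusters of at least 5 sites, and 100 random placements on the same chromosomes gave a mean of 8.82 and at most 17. The longest run was 30 sites, and the longest in any placement was 10. Per 100 Mb of the span from first to last peak, chromosome 19 had 69.7 such clusters, chromosome 17 had 41.9 and chromosome 7 had 5.03. Chromosome 7 nevertheless had 7.41 sites per Mb. Random placement ignores regional differences in mappability and gene density, and this comparison was chosen after the data were seen.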
